A study of Mus musculus with 15 samples.

How the data were processed

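RNA from sorted splenic Treg and Tconv of C57BL/6 control animals and of animals with a conditional Hpgd knockout under Foxp3-Cre was measured by sequencing in 15 libraries. Per the labels, cells were lysed in Qiazol and libraries were prepared with an Illumina TruSeq RNA kit from 10 ng of total RNA. Per the submitters' processing notes, TopHat was used and the genome build was mm10. The version of TopHat, the read counting and the gene annotation are not given in the sources used here. The deposited table holds a normalized signal for 17594 genes in 15 columns, 1 per library, which the authors obtained by dividing gene counts by 1 size factor per library. In every column all values are whole multiples of 1 step, so whole reads were recovered for 100% of values within a tolerance of 0.001. The file name holds the word DESeq, and the version is not given in the sources used here.

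Values were analysed in R 4.3.3 as log2(value + 1). Genes with a value of at least 10 in at least 3 libraries were kept, 11314 in all. A linear model with 4 group means was fitted to all 15 libraries in limma 3.58.1, with the spread moderated along a trend on mean level, and 5 contrasts were tested, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast are said to have passed. Treg and Tconv samples were treated as independent, because the labels do not say which samples share an animal. The p-values therefore measure the spread between samples. Replicates were numbered in the order of the sample records. The sample numbers of the labels run in adjacent pairs of 1 Treg and 1 Tconv sample of the same genotype. Such samples deviated from their group means together, in KO more than in WT, so a shared animal or shared handling is not excluded.

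The lists of genes, 11 of the alternatives in processing and the rule for naming genes were written before the data were examined. Named are, for each comparison, the 10 largest rises and 10 largest falls among genes that passed without overlap between the groups and with a mean of at least 50 over the libraries compared, leaving out predicted genes, pseudogenes and receptor segments. For the interaction the overlap was not considered. Hpgd, Foxp3, Il2ra, Ctla4 and Pparg, up to 4 members of each list with the smallest p, and genes named for another comparison could also be given. Other genes are named where a count of 5 or fewer calls for it or where the text says so. Of 21 lists, the mitochondrially encoded genes had 0 members in the table and were not tested, so 20 lists were tested with camera (preset correlation 0.01, and again with an estimated correlation), with adjustment over lists within a comparison. The other lists were Treg signature, naive T cell, activation and early response, T helper effector, prostaglandin and eicosanoid, PPAR gamma targets, visceral fat Treg, cAMP and CREB response, interferon, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, heat shock and isolation stress, markers of B cells, of CD8 T and NK cells, of myeloid cells and of erythroid cells and platelets, and sex-linked genes. Some genes stand in more than 1 list, such as Rora, Gata3 and Areg. The lists were also tested with fry, as planned, with the same adjustment. It asks whether the members of a list shift together in 1 direction and does not compare them with other genes.

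Gene positions, transcript lengths and GC contents came from GENCODE vM21 (GRCm38), matched by symbol: 17347 of 17594 symbols matched, 694 of them as older symbols, 30 were ambiguous and 217 unmatched. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Libraries held between 2.64 and 11.1 M reads. Reads carry no molecular identifiers, so limits from counts of 0 cover counting error only.

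The method was tested on simulated data made from these libraries. Each gene was drawn independently, without correlation between genes or samples and without trends on GC content or length. The results therefore say little about errors from such features of the real data. In the Treg KO against WT setting it found 38.1% of genes changed 1.5-fold, 80.8% of those changed 2-fold and 92.2% of those changed 4-fold. Of 171 calls 10 were false, counted over genes neither changed nor in the ribosomal protein list, which was shifted too. For Tconv KO against WT the shares were 47.2%, 82.6% and 93.2% with 7 false calls, and for the interaction 25.0%, 57.4% and 89.9% with 5. For Treg against Tconv they were 44.3%, 73.4% and 96.0% with 12 false calls in WT and 50.0%, 80.9% and 98.4% with 13 in KO.

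Besides leaving out each library in turn, 11 other ways of processing were fixed beforehand: edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 (Wald test) on the whole reads, pseudocounts of 8 and 0.1, no filter, a mean of at least 50, quantile normalization, TMM factors in place of the authors' scaling, a fit of only the groups compared, limma's library weights, and an estimated correlation in camera. A further 6 were chosen after seeing the data: reads thinned to 2635841 per library, removal of each library's trend on transcript length and on GC content, leaving out genes on X and Y or within 20 Mb of Hpgd, and a fit that takes samples with adjacent numbers as a block (correlation 0.248 within blocks). edgeR called 2444 genes in Treg KO against WT, 93 in Tconv KO against WT, 17 in the interaction, 2326 in Treg against Tconv of WT and 3462 in that of KO.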

Results

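RNA was sequenced from regulatory T cells (Treg, the CD4 T cells that carry the transcription factor Foxp3) and conventional CD4 T cells (Tconv), both sorted from mouse spleen on a C57BL/6 background. The knockout animals (KO) carried a conditional allele of Hpgd and a Foxp3-Cre-YFP driver, which restricts recombination to cells that express Foxp3. Hpgd encodes hydroxyprostaglandin dehydrogenase, the enzyme that starts the breakdown of prostaglandin E2. The control animals are labelled wild-type (WT). There were 4 Treg WT, 4 Treg KO, 3 Tconv WT and 4 Tconv KO libraries. Reads assigned to genes, in mega-reads (M reads), averaged 8.35 ± 1.48 M reads (SD, range 6.43 to 10.0) in Treg WT and 3.89 ± 0.896 M reads (2.64 to 4.71) in Treg KO. They averaged 8.77 ± 2.26 M reads (6.60 to 11.1) in Tconv WT and 5.40 ± 3.41 M reads (2.95 to 10.3) in Tconv KO. Between 12570 and 13945 genes had at least 1 read in a library. Levels below are normalized read counts, given as mean ± SD over the libraries of a group, and fold changes are log2 values ± SE.

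Foxp3 averaged 4502 ± 369 in Treg WT and 4046 ± 541 in Treg KO, against 17.1 ± 3.14 in Tconv WT and 40.8 ± 22.5 in Tconv KO. Hpgd (ENSMUSG00000031613.9, chromosome 8, 56294585 to 56321043 on the GRCm38 assembly, also called mm10) was close to undetectable everywhere. It had 1 read among the 33.4 M reads of the 4 Treg WT libraries and 0 reads in each of the other groups. Counts of 0 allow up to 0.193 reads per M reads in Treg KO, 0.114 in Tconv WT and 0.139 in Tconv KO, by counting error only. The loss of Hpgd transcript was therefore not detectable at this depth in either cell type. The sex-linked genes separated the genotypes. Xist, transcribed from the inactive X chromosome of females, averaged 15567 ± 2586 in Treg KO and 10118 ± 2052 in Tconv KO, against 1.84 and 1.67 in the WT groups. The Y-linked gene Ddx3y averaged 1361 ± 161 in Treg WT and 1419 ± 108 in Tconv WT and had 0 reads in all 8 KO libraries. Kdm5d and Eif2s3y also had 0 reads in all 8 KO libraries, and Uty had 1 read in them. All 7 WT libraries thus came from male cells and all 8 KO libraries from female cells, so sex and genotype cannot be told apart in these data. The sample numbers of the labels also run from 483 to 490 in the WT libraries and from 574 to 581 in the KO libraries, so a difference in collection or library preparation would coincide with genotype as well.

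**Figure D1:**
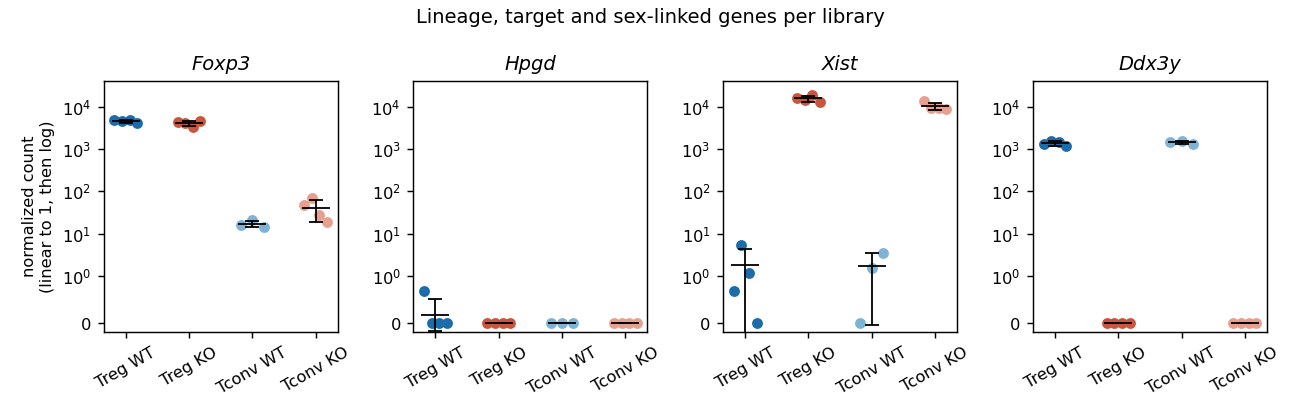
Normalized counts of Foxp3, Hpgd, Xist and Ddx3y in each library (points), with the mean and SD of each group (lines), on a scale that is linear up to 1 and logarithmic above. Foxp3 averaged 4502 in Treg WT, Ddx3y is at 0 in all 8 KO libraries, and Hpgd has a read in 1 Treg WT library.

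The first comparison asked which transcripts differ between Treg of the knockout animals and Treg of the control animals. Treg KO had more transcript of many genes of cell division, 23 of the 30 on the cell cycle list. Mki67, a marker of cycling cells, rose from 216 ± 79.9 to 898 ± 79.3 (n = 4 in each group, log2 fold change 2.11 ± 0.22, adjusted p = 2.3e-05). Top2a, which encodes the topoisomerase of mitotic chromosomes, rose by 1.79 ± 0.27 to 416 ± 96.3 (adjusted p = 7.0e-04). Of 30 genes of the cytoplasmic ribosome 24 fell: Rps19, for example, fell from 2918 ± 323 to 668 ± 134 (log2 fold change -2.14 ± 0.16, adjusted p = 6.8e-07). The Treg genes Foxp3, Il2ra and Ctla4 did not pass: Foxp3 changed by -0.16 ± 0.27 (adjusted p = 0.71), Il2ra, a chain of the interleukin-2 receptor, by 0.01 ± 0.13 (adjusted p = 0.95) and the inhibitory receptor Ctla4 by 0.46 ± 0.28 (adjusted p = 0.25).

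Of the 30 cell cycle genes, 23 rose and 0 fell in Treg KO, 24 and 0 adjusted over the list alone, with a median log2 fold change of 1.29; the list did not pass with an estimated correlation (adjusted p = 0.12 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 rose by 1.85 ± 0.29 (adjusted p = 9.7e-04), the cyclin Ccna2 by 2.48 ± 0.37 (adjusted p = 6.0e-04), the mitotic kinesin Kif11 by 2.12 ± 0.27 (adjusted p = 1.6e-04) and the replicative helicase subunit Mcm5 by 0.94 ± 0.10 (adjusted p = 3.0e-05). Of 18 tested genes of visceral fat Treg, 8 were higher, 0 lower and 10 did not pass, with a median of 0.80; the list did not pass with an estimated correlation (adjusted p = 0.37 with an estimated correlation). S100a4, a calcium-binding protein of migratory and effector cells, rose from 198 ± 6.00 to 571 ± 186 (log2 fold change 1.46 ± 0.23, adjusted p = 8.5e-04). The galectin genes Lgals1 and Lgals3 rose by 0.85 ± 0.14 and 1.45 ± 0.29 (adjusted p = 0.0010 and 0.0042). The T helper effector list had 4 of 19 members higher (Stat4, Ccr4, Rora and Il21) and 0 lower, with a median of 0.51; the list did not pass with an estimated correlation (adjusted p = 0.59 with an estimated correlation). The nuclear receptor Rora rose from 414 ± 33.3 to 914 ± 323 (adjusted p = 0.0061) and the chemokine receptor Ccr4 from 279 ± 27.2 to 544 ± 153 (adjusted p = 0.0028). The call of Il21 (3.08 ± 1.38 to 20.1 ± 15.2, adjusted p = 0.049) ended without any 1 library other than Treg KO replicate 4 (adjusted p up to 0.14) and under 6 other settings: edgeR (0.089), a pseudocount of 8 (0.12), no filter (0.069), a fit of only the Treg groups (0.074), thinned reads (0.089) and the GC trend removed (0.086). Stat4, which transmits interleukin-12 signals, rose by 0.45 ± 0.12 (adjusted p = 0.016), a call that ended with the GC trend removed (adjusted p = 0.065). Of 22 activation and early response genes, 6 rose and 0 fell, among them Tnfaip3, an inhibitor of NF-kappaB signalling (0.81 ± 0.16, adjusted p = 0.0045). As a set the activation list did not pass (adjusted p = 0.073 by camera).

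Of 16 naive T cell genes, 3 fell, 1 rose and 12 did not pass over all genes, with a median of -0.41. The list passed by camera with the preset correlation but not with an estimated correlation (adjusted p = 0.62 with an estimated correlation), nor without Treg KO replicate 1 (adjusted p = 0.105). Klf2, a transcription factor of resting T cells, fell from 886 ± 133 to 495 ± 136 (log2 fold change -0.87 ± 0.15, adjusted p = 0.0020). Igfbp4, which encodes a binding protein of insulin-like growth factors, fell by 1.34 on the log2 scale to 428 ± 186 (adjusted p = 0.011). Bach2, a repressor of effector genes, also fell (-0.62 ± 0.19, adjusted p = 0.033), while Il7r, the interleukin-7 receptor chain, rose (0.64 ± 0.21, adjusted p = 0.041). Adjusted over the list alone, 6 naive genes fell and 1 rose. With the GC trend removed Klf2 and Il7r no longer passed (adjusted p = 0.067 and 0.14), and Il7r also did not with no filter (0.058), in a fit of only the Treg groups (0.076), with library weights (0.17) or with the length trend removed (0.051). The call of Bach2 ended without any 1 of the 4 Treg WT libraries or Treg KO replicate 1 or 3, and that of Il7r without Treg WT replicate 1, 2 or 4 or Treg KO replicate 1, 3 or 4, with adjusted p up to 0.075 without Treg WT replicate 1 and 0.13 without Treg WT replicate 4.

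Of the 30 ribosomal protein genes, 24 fell and 0 rose in Treg KO, 25 and 0 adjusted over the list alone, with a median of -0.75; the list did not pass with an estimated correlation (adjusted p = 0.12 with an estimated correlation). Rps28 fell by 2.63 on the log2 scale to 165 ± 48.3 (adjusted p = 3.9e-07), and Rpl13 from 3675 ± 493 to 1098 ± 191 (adjusted p = 2.5e-06). Reads of these genes can be shared with their processed pseudogenes, so the level of any 1 of them is uncertain. Tmsb10, a thymosin that binds actin monomers, fell from 2434 ± 245 to 484 ± 70.5 (log2 fold change -2.34 ± 0.14, adjusted p = 5.9e-08). Of 27 genes of oxidative phosphorylation, 8 fell and 1 rose, 9 and 2 adjusted over the list alone, with a median of -0.12. The cytochrome c oxidase subunits Cox5b and Cox5a fell (-1.36 ± 0.18 and -0.96 ± 0.13, adjusted p = 2.2e-04 and 2.9e-04), whereas the complex I subunit Ndufa1 rose (0.61 ± 0.11, adjusted p = 0.0017). In glycolysis only Ldha, lactate dehydrogenase A, passed among 17 genes and it fell (-0.40 ± 0.06, adjusted p = 9.7e-04). In cholesterol synthesis Fdps fell (-0.87 ± 0.19, adjusted p = 0.0063) and Hsd17b7 rose (0.75 ± 0.19, adjusted p = 0.012) among 20 genes. With reads thinned to 1 depth Hsd17b7 no longer passed (adjusted p = 0.11).

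The lists closest to the study's question moved little in Treg KO. Of 14 tested genes of prostaglandin and eicosanoid synthesis, breakdown and signalling, 1 fell and 0 rose: Tbxa2r, the thromboxane receptor, went from 269 ± 15.7 to 145 ± 59.9 (log2 fold change -0.99 ± 0.25, adjusted p = 0.014), a call that ended with the GC trend removed (adjusted p = 0.10). The prostaglandin E2 receptors Ptger2 and Ptger4 did not pass (-0.10 ± 0.43 and 0.14 ± 0.17, adjusted p = 0.88 and 0.58). Of 17 tested PPAR gamma targets, 0 passed in limma in either direction (5 with an unadjusted p under 0.05, 0 in edgeR and 0 in DESeq2), and Pparg itself stayed below the minimum level for testing. Among 21 genes that respond to cAMP, the messenger of the prostaglandin E2 receptors, Crem and Rgs2 rose (0.65 ± 0.19 and 0.92 ± 0.20, adjusted p = 0.028 and 0.0068) and 0 fell. The call of Crem ended without Treg WT replicate 1 or 4 or Treg KO replicate 1, 3 or 4 (adjusted p up to 0.085), in a fit of only the Treg groups (0.061), with library weights (0.069), with thinned reads (0.055) and with the GC trend removed (0.096). Of 26 interferon-stimulated genes 2 rose (Ifih1 and Ddx58), 1 adjusted over the list alone, and 0 fell. With the GC trend removed Ifih1, Ddx58 and Prf1, named below, no longer passed (adjusted p = 0.25, 0.12 and 0.075). Ifih1 also did not pass with no filter, thinned reads or the length trend removed (0.061, 0.092 and 0.087), nor without any 1 library other than Treg KO replicate 4 (up to 0.12). Of 29 Treg signature genes, 1 fell, Ecm1, an extracellular matrix protein (987 ± 122 to 522 ± 123, adjusted p = 0.0049), and 0 rose. Of 19 heat shock and isolation stress genes 3 fell (Hspb1, Dnajb1 and the mitochondrial chaperonin subunit Hspe1, -0.83 ± 0.13, adjusted p = 6.8e-04) and 1 was lower adjusted over the list alone. The call of Hspb1 ended without any 1 library other than Treg KO replicate 1 (adjusted p up to 0.13) and under 6 other settings (0.055 to 0.22), and that of Dnajb1 without Treg WT replicate 1 or 2 or Treg KO replicate 1, 3 or 4 (up to 0.15) and under 5 other settings (0.062 to 0.081). Of 7 tested B cell markers 2 rose, the class II genes H2-Aa and H2-Eb1, and 4 adjusted over the list alone. H2-Eb1 went from 9.78 ± 4.26 to 72.7 ± 46.5 (adjusted p = 0.0058). Of 9 CD8 T and NK cell markers 1 fell (Prf1, -0.78 ± 0.23, adjusted p = 0.028), of 2 myeloid markers 0 passed in limma, edgeR or DESeq2 (0 with an unadjusted p under 0.05), and the 1 tested erythroid and platelet marker, Itga2b, fell (-1.43 ± 0.25, adjusted p = 0.0020). The call of Prf1 ended without Treg WT replicate 1 or 3 or Treg KO replicate 1, 2 or 3, and that of H2-Aa without replicate 1, 2 or 3 of either group, with adjusted p up to 0.084 without Treg WT replicate 3 and 0.10 without Treg WT replicate 1. With thinned reads both no longer passed (0.14 and 0.13), nor did Prf1 in a fit of only the Treg groups (0.087) or H2-Aa with a pseudocount of 0.1 (0.050). For the Treg KO lists given without a count adjusted over the list alone, that count was the same.

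Among the other named genes, the potassium channel subunit Kcnf1 rose from 4.19 ± 0.595 to 211 ± 59.0 (adjusted p = 7.6e-09). Lrrn3 rose by 2.23 ± 0.38 (adjusted p = 0.0017). The zinc finger gene Zfp868 on chromosome 8 (69610857 to 69625548) rose from 134 ± 11.7 to 466 ± 117 (adjusted p = 1.9e-05). The class I genes H2-Q6 and H2-L fell (-2.62 ± 0.27 and -3.74 ± 0.88, adjusted p = 2.3e-05 and 0.0095), although reads of this family map to several paralogs and their levels are uncertain. Cyp4f18, a cytochrome P450 of fatty acid metabolism, was chosen after its values were seen: it had 0 reads in all 7 WT libraries and averaged 98.0 ± 62.8 in Treg KO (adjusted p = 3.9e-07) and 1.49 in Tconv KO. It lies on chromosome 8 (71988482 to 72009626). The window of 20 Mb on either side of Hpgd held 19 genes past the threshold with more than a 2-fold change among 156 tested (12.2%), against 299 of 10689 elsewhere on the autosomes (2.80%, Fisher's exact test, two-sided, p = 1.4e-07, adjusted p = 4.2e-07 over 3 sets of genes). Of these 19 genes, 9 were higher in Treg KO, 1 lay within 10 Mb of Hpgd and 14 started between 68.4 and 72.6 Mb, where 99 of the 156 tested genes start.

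**Figure D2:**
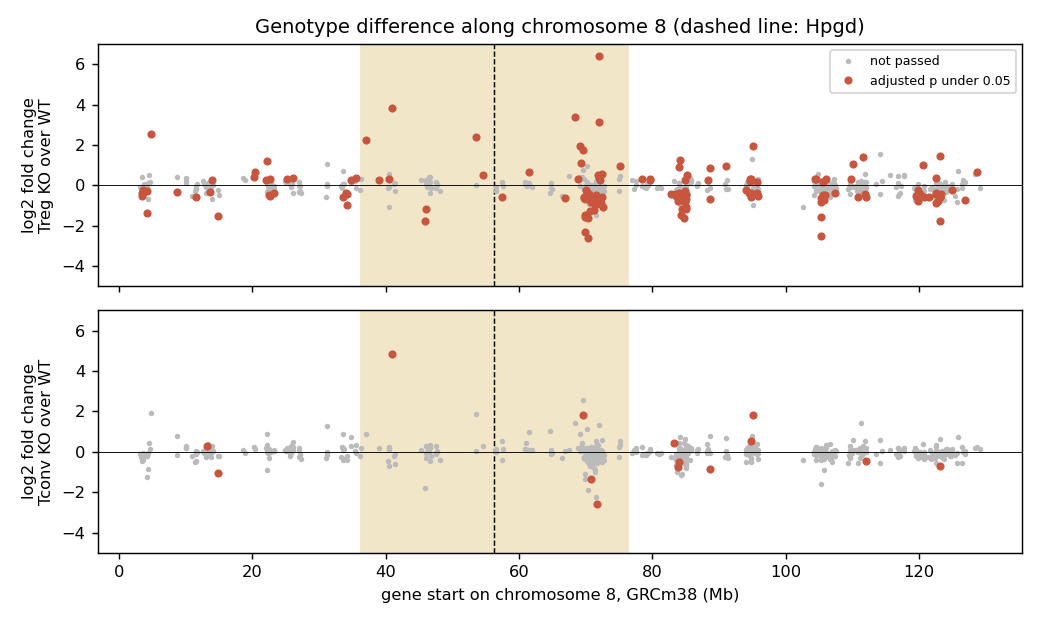
Log2 fold change KO over WT of each tested gene on chromosome 8 in Treg (top) and Tconv (bottom) against its start in Mb, with the dashed line at Hpgd, the shaded window of 20 Mb on either side and larger points for genes past the threshold. The window holds 57 genes past the threshold in Treg and 4 in Tconv.

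In all, 2431 of 11314 genes differed between Treg KO and Treg WT in limma, 1178 higher and 1253 lower in KO, of which 338 by more than 2-fold, and 4108 genes had an unadjusted p under 0.05. Set tests with the preset correlation of camera passed for 7 of 20 lists: naive T cell (adjusted p = 0.0080), T helper effector (0.0039), visceral fat Treg (1.9e-05), cell cycle (8.0e-14), oxidative phosphorylation (0.028), ribosomal proteins (1.3e-18) and the sex-linked genes (2.2e-08). With an estimated correlation 0 of them held, with adjusted p = 0.12 with an estimated correlation for cell cycle, 0.12 for ribosomal proteins and 0.37 for visceral fat Treg. The oxidative phosphorylation list no longer passed by camera once the trend on transcript length was removed (adjusted p = 0.687). Sets of other genes matched to this list on length and level were drawn after the results were seen. Of 100 such sets, 62 had a median as low as that of the 26 members with a known length (-0.11). By fry, visceral fat Treg (adjusted p = 0.014), cell cycle (1.2e-04), oxidative phosphorylation (3.2e-05), ribosomal proteins (1.0e-04) and the sex-linked genes (3.3e-16) passed. Of the same 7 lists, naive T cell (0.13) and T helper effector (0.11) did not. Across genes the fold change ran with GC content (Pearson r = -0.37 over 11222 genes, which are not independent replicates), from a median of 0.20 in the fifth of genes with the lowest GC content to -0.32 in the highest. With the GC trend of each library removed, 1502 genes passed, of which 1133 were among the 2431. Leaving out Treg WT replicate 1 or replicate 4 left 1393 and 1498, of which 1388 and 1465 were among the 2431.

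**Figure D3:**
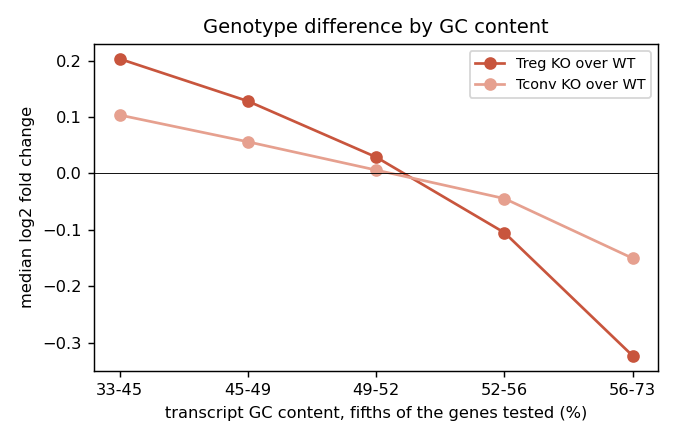
Median log2 fold change KO over WT in Treg and Tconv (lines) of the genes tested, in 5 bins of equal size by transcript GC content in percent. The medians fall from 0.20 to -0.32 in Treg and from 0.10 to -0.15 in Tconv.

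**Figure D4:**
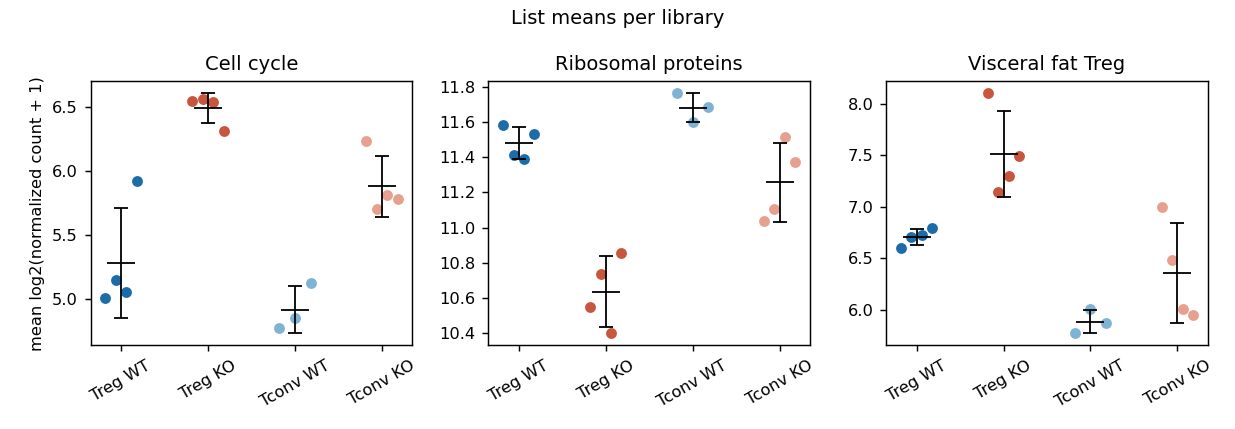
Mean log2 value of the cell cycle, ribosomal protein and visceral fat Treg lists in each library (points), with the mean and SD of each group (lines). The median log2 fold change in Treg was 1.29 for cell cycle, -0.75 for ribosomal proteins and 0.80 for visceral fat Treg.

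The same comparison in Tconv measured the genotype difference in the cells sorted as Tconv, where Foxp3 was low. Some cell cycle genes were higher in Tconv KO as well, 7 of 30, with 0 lower and 23 that did not pass (15 and 0 adjusted over the list alone), and a median of 0.84; the list did not pass with an estimated correlation (adjusted p = 0.17 with an estimated correlation). Mki67 went from 149 ± 19.6 (n = 3) to 435 ± 155 (n = 4, log2 fold change 1.49 ± 0.24, adjusted p = 0.0072). Rrm2 rose by 1.84 ± 0.32 and Ccna2 by 2.26 ± 0.40 (adjusted p = 0.012 and 0.013). Birc5, an inhibitor of apoptosis with a role in mitosis, rose from 6.03 ± 1.69 to 28.7 ± 4.61 (adjusted p = 0.0084). Of 30 ribosomal protein genes 4 fell, 0 rose and 26 did not pass (22 and 0 adjusted over the list alone), with a median of -0.43; the list did not pass with an estimated correlation (adjusted p = 0.17 with an estimated correlation). Rps27 fell from 712 ± 52.4 to 306 ± 73.9 (adjusted p = 0.0018) and Rpl18 by 0.96 on the log2 scale (adjusted p = 0.014), both uncertain because of their pseudogenes. Mtus1, a microtubule-associated gene on chromosome 8 (40990914 to 41133726), averaged 5.26 ± 2.52 in Tconv WT and 183 ± 84.9 in Tconv KO (adjusted p = 6.6e-05).

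Kcnf1 averaged 0.405 ± 0.36 in Tconv WT and 94.0 ± 31.8 in Tconv KO (adjusted p = 3.6e-09). Zfp868 rose by 1.81 ± 0.20 (adjusted p = 1.6e-04), close to its change in Treg (1.76 ± 0.18). The ubiquitin ligase Rnf157 rose from 57.5 ± 14.5 to 225 ± 35.2 (adjusted p = 2.4e-04). Kdm6a, an X-linked gene that escapes X inactivation, rose by 0.70 ± 0.10 (adjusted p = 0.0019), as it did in Treg (1.06 ± 0.09). Psme2, a proteasome activator subunit, rose by 0.84 ± 0.16 and Ifi30, a lysosomal thiol reductase, fell (-1.34 ± 0.25, adjusted p = 0.021 and 0.019). The ribosomal RNA precursor Rn45s fell from 15944 ± 3030.5 to 6421 ± 899.7 (adjusted p = 0.011). Hspe1 fell by 0.80 on the log2 scale (adjusted p = 0.011) and was the only 1 of 19 heat shock genes to pass over all genes, with 5 lower adjusted over the list alone. The inducible pair Hspa1a and Hspa1b did not pass (adjusted p = 0.14 and 0.14), and reads are shared between them. Foxp3, Il2ra and Ctla4 did not pass (adjusted p = 0.15, 0.64 and 0.58). Leaving out 1 library ended several calls: Mki67 without Tconv WT replicate 1 (adjusted p = 0.062), Birc5 without Tconv WT replicate 2 (0.063), Psme2 and Ifi30 without any 1 of the 3 Tconv WT libraries or Tconv KO replicate 1 (up to 0.13 and 0.12). So did Rn45s without Tconv WT replicate 2 or 3 (up to 0.082), Rpl18 without replicate 1 or 3 (up to 0.11) and Hspe1 without replicate 1 or 2 (up to 0.094). With reads thinned to 1 depth Birc5, Psme2 and Hspe1 no longer passed (adjusted p = 0.055, 0.055 and 0.055), and in a fit of the Tconv libraries alone Psme2 and Rpl18 did not (0.068 and 0.070).

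In Tconv 77 of 11314 genes passed in limma, 33 higher and 44 lower in KO, of which 32 by more than 2-fold, and 1358 genes had an unadjusted p under 0.05. Camera passed for 9 of 20 lists. They were cell cycle (adjusted p = 6.3e-16), ribosomal proteins (2.2e-18), heat shock (1.3e-05, lower), the sex-linked genes (2.2e-18), visceral fat Treg (4.0e-04), T helper effector (0.0014), Treg signature (0.021), cAMP response (0.047) and B cell markers (0.025). With an estimated correlation only the sex-linked genes held (adjusted p = 0.0033 with an estimated correlation). In the visceral fat Treg, T helper effector, Treg signature, cAMP and B cell lists 0 single genes passed in limma over all genes, with 1 T helper effector gene and 3 B cell markers adjusted over the list alone. Without Tconv KO replicate 1 the Treg signature, T helper effector, cAMP and B cell lists no longer passed (adjusted p = 0.993, 0.137, 0.084 and 0.0856), nor did the Treg signature (0.0676), cAMP (0.0676) and B cell lists (0.0621) without Tconv KO replicate 2. Without Tconv WT replicate 1 the Treg signature and cAMP lists no longer passed (0.128 and 0.115), and the cAMP list also not without Tconv WT replicate 3 (0.0511) or Tconv KO replicate 3 (0.05004), or with the length trend removed (0.0528). Single genes passed in 0 cases in limma in the naive, activation, prostaglandin, PPAR gamma, interferon, glycolysis, oxidative phosphorylation, cholesterol, CD8 and NK, myeloid and erythroid lists either. Over the 16 lists without a call, 26 of 265 members had an unadjusted p under 0.05, edgeR called 0 and DESeq2 5. The count fell to 22 without Tconv WT replicate 1, 27 without replicate 2 and 30 without replicate 3. DESeq2 on the whole reads called 236 genes and limma with library weights 307. By fry, cell cycle (adjusted p = 0.011), ribosomal proteins (0.031) and the sex-linked genes (6.5e-16) passed. The rest of the 9 lists past the camera threshold did not (0.17 to 0.55).

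The genotype differences of both cell types ran together across genes. Over all 11314 genes Pearson's r between the log2 fold changes in Treg and Tconv was 0.717, across genes that are not independent replicates. Without the 5 sex-linked genes it was 0.656, with a slope of 0.506 for Tconv on Treg. Of the 2426 other genes past the threshold in Treg, 2207 had the same sign in Tconv. Both comparisons shared 26 higher and 33 lower genes besides the sex-linked ones, against 3.33 and 4.42 with independent calls. Genes higher in Treg KO had a median of 0.40 in Treg and 0.15 in Tconv, and genes lower in Treg KO had medians of -0.53 and -0.21. The comparisons share no library, but all KO libraries are female and all WT libraries male in both. Treg and Tconv samples with adjacent numbers in the labels also moved together: the deviations from the group means of such samples had a mean Pearson's r of 0.392 over 4 pairs in KO (0.208 to 0.541), the highest of 24 ways to match them, and of 0.123 over 3 pairs in WT (0.016 to 0.21), which 2 of 24 ways reached. The correlation of fold changes, the overlap and its value with independent calls do not account for this dependence.

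**Figure D5:**
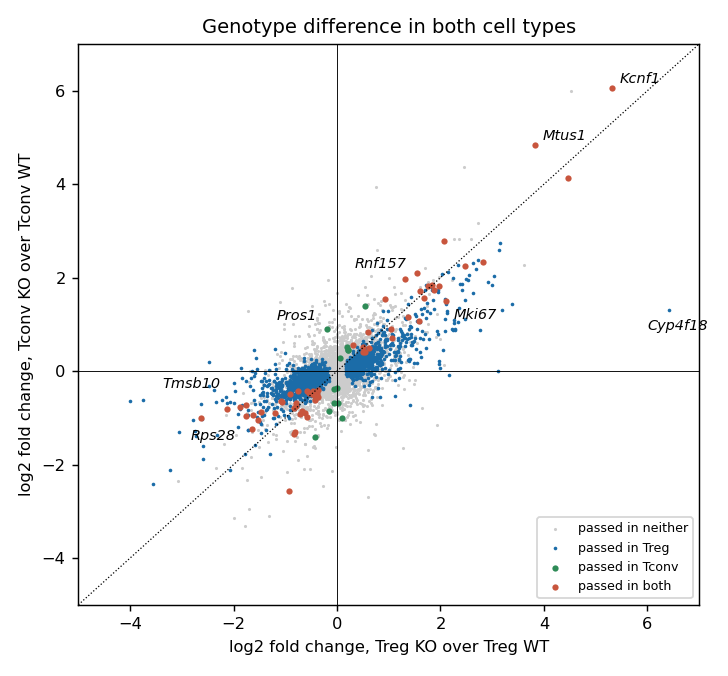
Log2 fold change KO over WT in Treg (horizontal) against that in Tconv (vertical) for each tested gene, coloured by whether it passed in Treg, in Tconv, in both or in neither, with the dotted line marking equal change. Xist and 4 Y-linked genes lie outside the axes, and Pearson's r over all 11314 genes was 0.717.

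The interaction asked whether the genotype difference differs between Treg and Tconv. Several ribosomal and mitochondrial genes fell more in Treg than in Tconv. Genes with transcripts under 700 nt as a whole also fell more in Treg (median log2 fold change -0.30) than in Tconv (-0.16). A shift that goes with transcript length therefore does not cancel in the interaction. Tmsb10 fell in Treg (-2.34 ± 0.14) and did not pass in Tconv (-0.66 ± 0.15), a difference of -1.67 ± 0.21 (n = 4, 4, 3 and 4 libraries, adjusted p = 0.0068). Atp5e and Atp5l, which encode small subunits of the mitochondrial ATP synthase, differed by -1.24 ± 0.17 and -1.23 ± 0.20 (adjusted p = 0.0088 and 0.030). The ribosomal protein gene Rps19 differed by -1.59 ± 0.23 and Rps28 by -1.62 ± 0.27 (adjusted p = 0.012 and 0.032). Cox5a fell in Treg (-0.96 ± 0.13) and did not pass in Tconv (0.13 ± 0.14), with a difference of -1.09 ± 0.19 (adjusted p = 0.034). Pros1, the anticoagulant protein S, did not pass in Treg (-0.18 ± 0.13, adjusted p = 0.32) and rose in Tconv (0.89 ± 0.14, adjusted p = 0.0063). The difference was -1.08 ± 0.19 (adjusted p = 0.034).

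Genes with a larger value in Treg included Hirip3, a histone chaperone partner (difference 0.89 ± 0.14, adjusted p = 0.030), Cyp4f18 (adjusted p = 0.0068) and Gm1821. Rps13, Rps23 and Rps27a differed by -1.11 ± 0.19, -1.04 ± 0.18 and -1.32 ± 0.23, each with an adjusted p of 0.034. In all, 17 genes passed in limma, 4 with a larger and 13 with a smaller value in Treg, and 963 had an unadjusted p under 0.05. Of the ribosomal protein list 1 gene passed (Rps19; 8 adjusted over the list alone) with a median of -0.38, and of the oxidative phosphorylation list 1 (Cox5a; 3 lower and 1 higher adjusted over the list alone). Camera passed for ribosomal proteins (adjusted p = 6.7e-10), cell cycle (0.0058, higher in Treg), visceral fat Treg (0.025, higher in Treg) and oxidative phosphorylation (0.028), and with an estimated correlation for 0 of these 4 lists (adjusted p = 0.20 to 0.98 with an estimated correlation). In the other 18 lists 0 genes passed in limma over all genes (23 of 292 members with an unadjusted p under 0.05, 0 called by edgeR and 2 by DESeq2). Adjusted over the list alone, 1 cell cycle gene was higher and 1 erythroid and platelet marker lower. Visceral fat Treg no longer passed without Tconv WT replicate 2 (0.0719), Treg KO replicate 1 (0.294), Tconv KO replicate 3 (0.126) or Tconv KO replicate 4 (0.186), nor oxidative phosphorylation without Tconv WT replicate 2 (0.0719), Treg KO replicate 1 (0.0564), Treg KO replicate 4 (0.0594) or Tconv KO replicate 4 (0.109) or with the length trend removed (0.196). The count ranged from 3 without Tconv WT replicate 2 to 23 without Tconv KO replicate 1. It was 5 without each of Tconv WT replicates 1 and 3, Treg WT replicates 1, 2 and 4 and Treg KO replicate 2, and 7 without Treg KO replicate 1 or Tconv KO replicate 3. Of the 12 genes chosen by the rule, 11 (all but Tmsb10) lost their call without at least 1 of the 15 libraries, with adjusted p up to 0.15. By fry, of the 4 lists past the camera threshold, oxidative phosphorylation passed (adjusted p = 0.017) and the others did not (0.32 to 0.97). With adjacent sample numbers taken as a block, 44 genes passed. With reads thinned to 1 depth Hirip3, Rps27a, Atp5l and Cox5a no longer passed (adjusted p = 0.16, 0.059, 0.056 and 0.10), with the length trend removed Rps23, Rps27a and Cox5a did not (0.061, 0.061 and 0.094), and Pros1 did not after quantile normalization (0.074), with a pseudocount of 8 (0.053) or with no filter (0.058).

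The comparison of control Treg with control Tconv gave the cell type difference without the knockout. The genes that define Treg led it: Foxp3 was higher by 7.97 ± 0.30 (adjusted p = 1.5e-10) and Il2ra averaged 4042 ± 145 in Treg (n = 4) and 55.8 ± 10.5 in Tconv (n = 3, adjusted p = 1.6e-13). Lrrc32, which anchors latent TGF-beta on the cell surface, averaged 2219.7 ± 155 in Treg and 3.13 ± 2.01 in Tconv (adjusted p = 2.2e-07). The integrin Itgae was higher by 6.77 ± 0.38 and Ctla4 by 2.97 ± 0.31 (adjusted p = 1.4e-08 and 5.1e-06). Of 29 Treg signature genes 25 were higher and 0 lower, with a median of 2.65. Il1rl1, the interleukin-33 receptor, was higher by 5.42 ± 0.44 and the lectin-like receptor Klrg1 by 4.83 ± 0.37 (adjusted p = 5.0e-07 and 2.6e-07). The surface proteoglycan Sdc4 averaged 135 ± 17.5 in Treg and 3.46 ± 0.757 in Tconv, and the dynein gene Dnah7a 319.6 ± 55.0 and 3.98 ± 1.61. The chemokine receptors Ccr8, Ccr6 and Ccr4 were higher in Treg (4.36 ± 0.44, 2.49 ± 0.31 and 1.10 ± 0.19). Among receptors of prostaglandin E2, Ptger2 was higher in Treg (578 ± 69.8 against 167 ± 19.7, adjusted p = 0.012) and so was Ptger4 (0.84 ± 0.18, adjusted p = 0.0043). The call of Ptger2 ended without Tconv WT replicate 1 (adjusted p = 0.056).

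Genes lower in control Treg included the phosphodiesterase Pde3b, which degrades cAMP (32.2 ± 6.12 in Treg against 1535 ± 90.8 in Tconv, adjusted p = 6.4e-09). The receptor of vasoactive intestinal peptide, Vipr1, and the amyloid precursor gene App were lower (log2 fold change -3.74 ± 0.30 and -4.38 ± 0.26, adjusted p = 4.2e-07 and 2.1e-08). Pdlim4 averaged 0.787 in Treg and 193 ± 47.5 in Tconv, and the granzyme gene Gzmk 0.318 and 125 ± 34.8. The helper cytokine Il21, the chemokine Ccl5 and the CD40 ligand Cd40lg were lower (log2 fold change -5.73 ± 0.73, -3.77 ± 0.57 and -2.15 ± 0.12, adjusted p = 4.6e-05, 2.1e-04 and 1.0e-08). Naive T cell genes were lower in 11 of 16 cases and higher in 0, with a median of -0.85, for example Tcf7 (-1.30 ± 0.09), Lef1 (-1.36 ± 0.20) and Dapl1 (-3.74 ± 0.50). Of 9 CD8 T and NK cell markers 7 were lower and 0 higher, with a median of -3.45: Klrk1 averaged 0.538 in Treg and 70.2 ± 31.0 in Tconv, and Klrd1 0.344 and 47.4 ± 13.5.

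In control cells 2046 genes passed in limma, 1134 higher and 912 lower in Treg, of which 849 by more than 2-fold, and 3353 had an unadjusted p under 0.05. Counts over the other lists, higher and lower in Treg, were 7 and 2 of 22 for activation, 5 and 5 of 19 for T helper effector, 5 and 1 of 14 for prostaglandin and eicosanoid genes, 4 and 1 of 17 for PPAR gamma targets, 7 and 4 of 18 for visceral fat Treg and 7 and 1 of 21 for cAMP response. They were 6 and 2 of 26 for interferon, 3 and 1 of 30 for cell cycle, 2 and 1 of 17 for glycolysis, 0 and 2 of 30 for ribosomal proteins, 2 and 0 of 19 for heat shock, 3 and 0 of 7 for B cell markers and 0 and 1 of 2 for myeloid markers. In the oxidative phosphorylation, cholesterol, erythroid and sex-linked lists 0 genes passed in limma (4 of 53 with an unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2). Adjusted over the list alone, the counts were 26 and 0 for Treg signature, 0 and 12 for naive T cell, 13 and 2 for activation, 6 and 6 for T helper effector, 8 and 5 for visceral fat Treg, 8 and 3 for cAMP response and 8 and 2 for interferon. They were 2 and 1 for cell cycle, 2 and 2 for glycolysis, 0 and 0 for ribosomal proteins, 4 and 0 for B cell markers, 0 and 8 for CD8 T and NK cell markers and 1 and 1 for myeloid markers, and the same as over all genes for the rest. Camera passed for Treg signature (adjusted p = 1.7e-29), naive T cell (2.1e-07), CD8 T and NK cell markers (1.7e-07), B cell markers (0.0022), activation (0.0068), cAMP response (0.028) and ribosomal proteins (0.0068). Of these, Treg signature and CD8 T and NK cell markers held with an estimated correlation (adjusted p = 0.024 and 0.0074 with an estimated correlation). The ribosomal protein list no longer passed by camera after quantile normalization (0.156). By fry, activation and ribosomal proteins did not pass (adjusted p = 0.24 for both). The other lists past the camera threshold passed by fry (adjusted p up to 0.029). A fit of the Treg WT and Tconv WT libraries alone called 3990 genes and limma with library weights 4330.

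The same cell type comparison was made in knockout animals. Foxp3 was higher in Treg by 6.75 ± 0.27 and Il2ra by 6.01 ± 0.13 (n = 4 in each group, adjusted p = 3.9e-10 and 7.5e-14). Lrrc32 averaged 1109.5 ± 535 in Treg KO and 6.58 ± 7.59 in Tconv KO (adjusted p = 4.5e-07). Of 29 Treg signature genes 26 were higher and 0 lower, with a median of 2.62. Cd83, an activation marker, was higher by 3.61 ± 0.42 and Zc3h12c, a regulator of RNA decay, by 5.09 ± 0.33 (adjusted p = 1.3e-05 and 4.2e-08). Gata3, the T helper regulator, was higher by 1.31 ± 0.17 and the growth factor Areg averaged 33.1 ± 29.3 in Treg KO and 0.57 in Tconv KO (adjusted p = 3.4e-05 and 6.4e-05). Ptger2 and Ptger4 were again higher in Treg (1.58 ± 0.43 and 0.91 ± 0.17, adjusted p = 0.011 and 8.8e-04), and Pde3b was lower (-4.66 ± 0.27, adjusted p = 1.7e-08). Mki67 was higher in Treg KO than in Tconv KO by 1.10 ± 0.22 and Mcm5 by 0.59 ± 0.10 (adjusted p = 0.0015 and 4.6e-04). Igfbp4 and Klf2 were lower (log2 fold change -3.07 ± 0.32 and -1.20 ± 0.15, adjusted p = 5.3e-06 and 3.2e-05), while Rps19 and Tmsb10 were lower too (-1.79 ± 0.16 and -1.87 ± 0.14, adjusted p = 9.2e-07 and 1.9e-07).

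In knockout cells 3558 genes passed in limma, 1793 higher and 1765 lower in Treg, of which 1078 by more than 2-fold, and 4829 had an unadjusted p under 0.05. The WT and KO comparisons shared 941 genes higher in Treg and 715 lower, against 179.7 and 142 with independent calls. Both measure the same cell type difference and come from 1 fit, so an excess over independent calls carries little weight. Counts over the lists, higher and lower in Treg KO, were 0 and 13 of 16 for naive T cell, 11 and 2 of 22 for activation, 5 and 7 of 19 for T helper effector, 4 and 1 of 14 for prostaglandin and eicosanoid genes, 2 and 0 of 17 for PPAR gamma targets, 8 and 2 of 18 for visceral fat Treg and 7 and 3 of 21 for cAMP response. They were 6 and 3 of 26 for interferon, 8 and 0 of 30 for cell cycle, 3 and 1 of 17 for glycolysis, 1 and 6 of 27 for oxidative phosphorylation, 1 and 4 of 20 for cholesterol synthesis, 0 and 21 of 30 for ribosomal proteins and 2 and 1 of 19 for heat shock. Of the marker lists, 5 and 0 of 7 B cell, 0 and 8 of 9 CD8 T and NK, 0 and 1 of 2 myeloid and 0 and 1 of 1 erythroid markers passed, and 0 of 5 sex-linked genes passed in limma (0 with an unadjusted p under 0.05, 1 called by edgeR and 1 by DESeq2). Adjusted over the list alone, the counts were 14 and 2 for activation, 7 and 7 for T helper effector, 9 and 2 for visceral fat Treg, 8 and 3 for cAMP response, 7 and 4 for interferon, 2 and 1 for glycolysis, 0 and 22 for ribosomal proteins and 1 and 1 for myeloid markers, and the same for the rest. The T helper effector median was -0.16 although camera placed the list higher in Treg (adjusted p = 0.73). Camera passed for Treg signature (adjusted p = 7.0e-22), naive T cell (4.6e-08), ribosomal proteins (2.6e-09), CD8 T and NK cell markers (2.0e-06), cell cycle (2.8e-04), activation (0.0016), B cell markers (0.0016) and visceral fat Treg (0.0052). With an estimated correlation only CD8 T and NK cell markers held (adjusted p = 0.017 with an estimated correlation). By fry all the lists past the camera threshold passed (adjusted p up to 0.033). A fit of the Treg KO and Tconv KO libraries alone called 2042 genes.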

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

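The tests of other splits of the libraries for the 2 genotype comparisons and for Treg against Tconv of WT were fixed before their results were seen. The predictions for depth were written before their own results were seen, although thinning of reads was chosen after seeing the data. The tests of transcript length, GC content, sex, a linked segment and deletion in Foxp3-expressing cells, and the splits for the interaction and for Treg against Tconv of KO, were chosen only after the results were seen.

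Cell cycle genes were higher and ribosomal protein genes lower in knockout Treg, with medians of the same sign in knockout Tconv (0.84 and -0.43). By camera with an estimated correlation neither list passed in Treg (adjusted p = 0.12 for both) or in Tconv (0.17 for both). Neither passed in the interaction (0.98 for cell cycle and 0.57 for ribosomal proteins). The 5 sex-linked genes did not pass that test in Treg either (0.077). By fry both lists passed in Treg (adjusted p = 1.2e-04 for cell cycle and 1.0e-04 for ribosomal proteins) and in Tconv (0.011 and 0.031). They did not pass by fry in the interaction (0.97 and 0.32). For the cell cycle genes, the median log2 fold change in Treg was 1.42 with reads thinned to 1 depth, against 1.29 before. It was 1.25 with the length trend removed and 1.14 with the GC trend removed, which argues against each of these trends as the whole cause. Random thinning keeps the share of each gene on average, so it bears only on the number of reads. It cannot decide on other differences that go with depth. All 8 knockout libraries showed high Xist and no more than 1 Y-linked read, so sex and genotype cannot be told apart as sources of the cell cycle difference. A different state of the animals or of processing, which the sample numbers would also align with genotype, stays open and untested, as does an effect of Hpgd loss.

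For the ribosomal protein genes, the median in Treg was -0.75, and it was -0.74 with reads thinned to 1 depth. Thinning at random keeps the share of each gene, so the median of such abundant transcripts could hardly move. The test therefore cannot decide on differences that go with depth. With the length trend removed the median was -0.56, so a general trend on transcript length may account for part of the difference but not for all of it. The trend was fitted over all genes, the ribosomal protein genes among them, so the size of that part was not measured. Of 100 sets of other genes matched on length and level, 0 had a median as low in Treg, and their own median was -0.23. These sets could hold ribosomal protein genes outside the list, such as Rps28, which also fell. The value of -0.23 is therefore not a measure of transcript length alone. Again all 8 knockout libraries are female, so sex cannot be told apart from genotype here. A loss of short transcripts in library preparation that bears on this family more than on matched genes was not tested.

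The window of 20 Mb on either side of Hpgd on chromosome 8 held more 2-fold changes in Treg than elsewhere (Fisher's exact p = 1.4e-07). Of 347 autosomal windows with other centres, 1 held a larger share (13.2%, against 12.2% around Hpgd). The genes were not centred on Hpgd: of 19, 18 lay more than 10 Mb away, and 14 started between 68.4 and 72.6 Mb, a stretch that holds 99 of the 156 tested genes. All 8 knockout libraries are female, so sex cannot be told apart from genotype here either. The excess stayed with the GC trend removed (14 of 156 genes, 8.97%, against 2.14% elsewhere, exact p = 1.0e-05). Of the 19 genes, 18 had the same sign in Tconv, and so had 285 of 299 such genes elsewhere on the autosomes. Along their direction in Treg, the 19 genes had a median log2 fold change of 0.88 in Tconv (0.80 to 1.05 with 1 library left out). Deletion of Hpgd in Foxp3-expressing cells had predicted a median near 0, but such genes elsewhere also moved, with a median of 0.68. The change in Tconv as a share of that in Treg had a median of 0.447 in the window and 0.454 elsewhere (Wilcoxon rank-sum test, n = 19 and n = 299 genes, p = 0.93). The Tconv values thus do not set the window apart, and deletion of Hpgd in Foxp3-expressing cells stays open. A segment of another strain linked to the targeted allele may be the source, but the calls in Tconv leave this open: 4 of 156 genes passed against 62 of 10689 (exact p = 0.0149), yet 22 of 347 windows held as large a share, 9 of them among the 18 windows of chromosome 8. The rest of chromosome 8 also held more calls in Tconv (10 of 448 genes, 2.23%) than the other autosomes (52 of 10241, 0.508%, exact p = 2.3e-04), so the excess in Tconv is not confined to the window.

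For the 2431 genes in Treg KO against WT, 1 of the 35 splits of the 8 libraries, the real one, gave as many. The highest other split gave 0. For the 77 genes in Tconv it was 1 of 35 splits (highest other 15). This argues against chance but does not exclude it, since 1 of 35 is the smallest share possible. Other splits also mix the genotypes, which adds their difference to the spread. For the 2046 genes in Treg against Tconv of WT it was 1 of 35 with the samples taken as independent (highest other 9). The 8 splits that part the 3 pairs of adjacent numbers allow no share under 12.5%, so chance stays undecided there. For the 3558 genes of KO, samples with adjacent numbers deviated together, and the 8 splits that part all 4 such pairs are too few for a share under 0.05: the real one gave 3558 and the highest other 0. Among all 35 splits, which disregard the pairs, the highest other gave 1428. That split exchanged only Treg KO replicate 4 for Tconv KO replicate 1, so it kept part of the cell type difference. The source of its count was not tested. For the 17 genes of the interaction the additive effects of cell type and genotype were taken out first, a form chosen after the first results. Of 100 drawn splits 1, the real one, gave as many, and the highest other gave 2. Chance is thus unlikely here but not excluded. With these effects left in, as first planned, 3 of 100 splits gave as many and the highest other gave 1079, since such splits move the genotype differences into the interaction or its spread. With adjacent numbers kept together it was 1 of 35 splits, and the highest other gave 0.

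A sample lay far from the others of its group of 4 by Dixon's test in 33 of 429 groups tested (7.69%). Chance gives about 1 in 20 (5%) for independent, normally distributed values, which need not hold for these counts. Where all other libraries of a group had 0 reads, any read was flagged, as for Uty, Areg and Hspb1. The shares can therefore not be compared. Treg WT replicate 4 had the highest mean log2 value of the cell cycle list (5.92, others at most 5.15) and of the B cell markers (5.72, others 4.97 to 5.02), and the highest Rrm2 (79.8), Top2a (217) and Birc5 (25.7) but the lowest Pros1 (145). Treg KO replicate 4 had the lowest mean of the cell cycle list (6.32, others 6.54 to 6.56) and the highest Rps19 (868), Rps27 (202), Prf1 (58.8) and App (18.7). Treg WT replicate 3 had the highest H2-L (236), Ecm1 (1169) and Pde3b (41.3) and the lowest Rps27a (1108), Lrrc32 (1988) and Ryr2 (60.5). Treg KO replicate 3 had the lowest mean of the erythroid and platelet markers (2.41) and Rps13 (396) and the highest Mki67 (1017) and Ctla4 (4266). Treg KO replicate 1 had the lowest Mcm5 (490.3) and the highest Gzmk (39.2). Treg KO replicate 2 held the single Uty read (1.21), and Treg WT replicate 2 the lowest Bach2 (832). In Tconv KO, replicate 1 had the highest Mki67 (668) and H2-Eb1 (19.2) and the lowest Bach2 (607) and Hsd17b7 (76.9), replicate 2 had the lowest Zfp868 (351) and the only Areg reads (2.28), and replicate 3 had the highest Rpl18 (1857) and the only Hspb1 reads (5.91).

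The genotype difference itself differed between Treg and Tconv for 17 genes by the interaction test. The differences of the log2 fold changes were -1.67 for Tmsb10, -1.24 for Atp5e, -1.23 for Atp5l, -1.09 for Cox5a and -1.08 for Pros1. For ribosomal protein genes they were -1.59 for Rps19, -1.62 for Rps28, -1.11 for Rps13, -1.04 for Rps23 and -1.32 for Rps27a. For Hirip3, Arhgap11a and Gm1821 they were 0.89, 1.04 and 0.71, and for Cyp4f18 the fitted difference of 5.11 rests on groups at 0 reads and depends on the pseudocount. The call of Arhgap11a ended with thinned reads (adjusted p = 0.059), with no filter (0.063) and with the length trend removed (0.056). Of the lists, ribosomal proteins (adjusted p = 6.7e-10), cell cycle (0.00583), visceral fat Treg (0.0255) and oxidative phosphorylation (0.0280) differed by camera, 0 of them with an estimated correlation.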

How the results depend on the processing

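The settings with thinned reads, length or GC trends removed, genes on X and Y or near Hpgd left out, and adjacent sample numbers as a block were chosen only after the results were seen.

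No named gene or list that passed changed direction under the settings run. The number of genes in Treg KO against WT moved by over 1.5 times under 1 setting, the GC trend removed (1502, against 2431, with 1133 in both). In Tconv it was 236 with DESeq2, 307 with library weights, 32 in a fit of only the groups compared, 45 with the length trend removed and 50 without X and Y genes, against 77. The interaction gave 88 genes with DESeq2, 56 with library weights, 9 with thinned reads, 39 with the GC trend removed and 44 with adjacent sample numbers as a block, against 17. Treg against Tconv of WT gave 3990 in a fit of only the groups compared and 4330 with library weights, against 2046, and that of KO gave 2042 in a fit of only the groups compared, against 3558. Pearson's r between the genotype differences was 0.799 with a mean of at least 50, 0.624 with thinned reads and 0.657 without X and Y genes, against 0.717. The causes were not tested.

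Leaving out 1 library gave 1393 (Treg WT replicate 1) to 2743 (Treg KO replicate 2) genes in Treg KO against WT, 22 (Tconv WT replicate 1) to 105 (Tconv KO replicate 4) in Tconv, 3 (Tconv WT replicate 2) to 23 (Tconv KO replicate 1) in the interaction, 1407 to 1726 in Treg against Tconv of WT and 2907 to 3897 in that of KO, with r from 0.644 to 0.728. Other counts that moved by over 1.5 times were 1498 without Treg WT replicate 4 in Treg KO against WT, and 27 and 30 without Tconv WT replicates 2 and 3 in Tconv. In the interaction they were 5 without each of Tconv WT replicates 1 and 3, Treg WT replicates 1, 2 and 4 and Treg KO replicate 2, and 7 without Treg KO replicate 1 or Tconv KO replicate 3. Fewer libraries are in these fits.

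Among named genes that passed, 17 of 60 in Treg KO against WT no longer passed under at least 1 other setting and 12 when a library was left out. The counts were 11 and 14 of 26 in Tconv, 7 and 11 of 12 in the interaction, 8 and 10 of 68 in WT and 12 and 4 of 80 in KO. Of the lists past the camera threshold, 7, 9, 4, 7 and 8 in the same order, 6, 5, 2, 7 and 8 passed in every fit with 1 library left out, and 0, 1, 0, 2 and 1 with an estimated correlation. Depth limits Hpgd, which had 1 read in all.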

Other observations

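No test in this part was chosen after a result was seen; it gives levels and results of the comparisons already described. Markers of other blood cells were measured in the sorted populations. Ms4a1 and Ebf1, which mark B cells, averaged at most 2.34 and 0.669 in any group, while Cd22, of the same list, averaged between 94.9 and 157 in each group. Cd74, the invariant chain of class II molecules, averaged 531 ± 83.6 in Treg WT, 985 ± 409 in Treg KO, 35.2 ± 4.01 in Tconv WT and 82.1 ± 39.9 in Tconv KO. Cd79b, a chain of the B cell receptor complex, averaged 78.3 ± 4.95, 135 ± 22.2, 4.91 ± 2.80 and 11.5 ± 6.59 in the same order. Cd8a averaged at most 1.62 in any group, but Cd8b1, the other CD8 chain, averaged between 59.4 and 73.3 in each group. Eomes, a transcription factor of cytotoxic and memory cells, averaged 169 in Tconv WT and 364 in Tconv KO against 14.5 and 23.8 in Treg. Its mean in Tconv KO rests in large part on 1 library, at 778. Between the Tconv groups 0 of the 9 tested CD8 T and NK cell markers passed. Nkg7, a granule gene, averaged 316 and 455 in Tconv and 87.9 and 110.2 in Treg. The myeloid genes Lyz2 and Csf1r averaged at most 2.57 and 5.92 in any group, but of the same list Cst3 averaged between 151 and 211 in each group and Itgam 21.8 in Tconv WT and 22.2 in Tconv KO.

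Among prostaglandin receptors, Ptger1 averaged 583 ± 102 in Treg WT, 355 ± 141 in Treg KO, 649 ± 141 in Tconv WT and 333 ± 105 in Tconv KO. Its genotype difference did not pass in Treg (adjusted p = 0.069) or in Tconv (adjusted p = 0.22). Hpgds, a prostaglandin D synthase, averaged 53.8 ± 17.6 in Treg KO and 21.7 ± 7.99 in Tconv KO. Among heat shock transcripts, Hspa1b averaged 984 ± 426 in Tconv WT and 119.5 ± 74.2 in Tconv KO, a difference that did not pass. By camera the heat shock list was lower in Tconv KO (adjusted p = 1.3e-05), but it did not pass with an estimated correlation (0.41).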
